A study of Mus musculus with 221 samples.

How the data were processed

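The data are gene expression tables from mouse cells, 29 bulk libraries in 8 groups and 192 single-cell libraries in 5 groups. Per the labels, bulk RNA was extracted with TRIzol, copied to cDNA with a SMARTSeq v4 kit and made into libraries with Nextera XT. Single cells were captured on the Fluidigm C1 system, which isolates cells in microfluidic chambers, and their libraries were also made with Nextera XT. Each sample was grouped by its title and its labelled sort gate, and every deposited sample was used.

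The bulk table holds expected counts deposited by the authors, one per gene symbol and library, with no normalization between libraries. Of its values above 0, 63.7% are not whole numbers. For the bulk samples the authors name bcl2fastq 2.20, STAR 2.5.3a, DESeq2 1.20 and the genome build GRCm38.p5, without saying what each was used for. The single-cell table holds estimated transcripts per cell from the Census method, which the authors had already scaled within each cell. These are neither reads nor molecules counted by barcode, so the read depth of the single cells is unknown. For those cells the authors name CASAVA 1.8.2, Salmon and the same build. The annotation behind either table is not stated. Coordinates, gene types and gene lengths were taken from a GENCODE annotation of GRCm38, which may not be the release the authors used.

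The bulk table has 32545 lines, of which 1 is blank and 27 carry a symbol that a spreadsheet had turned into a date. These 27 held at most 0.415% of the counts of a library and were left out, so March1 and Sept3 could not be measured in bulk. The remaining 32517 genes were rounded to whole counts. Single-cell values were joined by Ensembl gene number, and 51633 of 51912 matched a symbol. Where several numbers shared 1 symbol, as held for 143 numbers, the values were added. All 338 genes of the fixed lists were found in the single-cell table, 1 of them by an older symbol.

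Bulk totals ran from 1.18 to 9.83 per library, in units of 1e6 counts. A gene with no counts in a group was given a floor of 3 counts over that group, and folds against it are lower bounds. This floor was 0.22 counts per 1e6 (CPM) for MEFs, 0.13 for day 5, 0.35 for day 9, 0.28 for cDC1, 0.29 for cDC2 and 0.48 for pDC. Floors and binomial intervals cover counting error only, since reads copied by PCR are not independent molecules.

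Genes were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by trimmed mean of M values (TMM), genes were filtered by filterByExpr with the groups, and a robust quasi-likelihood model with 1 coefficient per group was fitted to all 29 libraries. This left 13434 genes, with a common biological coefficient of variation of 0.205. A separate edgeR fit of the 13 libraries of days 5, 7, 8 and 9, with day as a number, tested 12053 genes for a steady trend. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. Standard errors (SE) of log2 folds were taken as the fold divided by the square root of its F statistic, an approximation. Expression levels are CPM of the library total, given as mean ± SD. These levels, the floors and the bounds set by them are not TMM-scaled, so ratios of levels differ from the fitted folds.

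The 25 gene lists, the comparisons, the tests, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 on voom values with its preset correlation between genes, adjusted over the lists of a comparison, and again with a correlation estimated for each list. A list call stands for the preset correlation unless the other p is given. Members were counted as risen or fallen after adjustment over all genes, and again adjusted over the list alone. The lists cover the transduced factors, cDC1, cDC2, pDC and pan-cDC genes, haematopoietic genes, MHC class I and II presentation, co-stimulation and maturation, innate sensors, interferon-stimulated genes, and cytokines and chemokines. They also cover extracellular matrix, mesenchymal regulators and receptors, contractile cytoskeleton, cell cycle, p53 and senescence, and 8 sets of markers of other cell types.

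Genes were named by rule. The transduced factors and the genes of the sort gates were always named. For each list in the comparisons of day 9 with MEF, day 5 and cDC1, and in the trend, up to 4 members with the largest fold in the main direction and the largest in the other direction could be named, at 10 CPM or more. If none passed, the most abundant member could be. The 5 largest rises and 5 largest falls without overlap between libraries were added, at 20 CPM or more in the higher group, passing over gene models and pseudogenes. For single cells the same genes were used, with the 5 genes per direction that differed most in share of cells.

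Subset signatures were genes at least log2 1 higher in 1 splenic subset than in each of the others, from splenic libraries alone. Similarity was Spearman's correlation across the 13434 genes between a library and the mean of a reference group, leaving a library out of its own mean. Genes are not independent replicates, so no p-value was taken from these correlations, and the difference of day 9 and day 5 was tested with an exact permutation test over libraries. For single cells a gene counted as detected at a value above 0, with 95% exact binomial intervals, and no test was made between groups, because the labels name no culture or animal and each group is therefore 1 sample.

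The procedure was tested on simulated data with known changes. Of 100 genes changed by log2 1, 66% were recovered, and of 100 changed by log2 2, 94%, with 9 false calls among 169. For the trend, 81% of 200 genes with a slope of 0.3 per day were recovered. All simulated groups were drawn from the MEF profile, with 200 genes changed, as many up as down and all expressed in MEFs. The real comparison of day 9 with MEF called 53.8% of genes, so these rates cannot be carried over to it. Libraries within a group were checked for duplicates over 40 pairs and none were copies. The replicate numbers in the titles were not taken as pairs, since in no comparison did all pairs of the same number correlate above 0.1. A partly shared batch is not excluded by this. Number 3 of MEF correlated with number 3 of day 8 at 0.294 and of day 9 at 0.209, but of day 7 at -0.294. The tilt with gene length described below, measured against each library's own group, was -0.2, -0.218, -0.141 and 0.206 for number 3 of MEF, day 8, day 9 and day 7. Its signs match those of the correlations, which therefore need not reflect a shared batch.

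Alternatives comprised DESeq2 size factors, library size alone, no low-count filter, the DESeq2 1.42.0 Wald test, limma-voom, fits of only the groups compared, the replicate number as a block, each library or day left out, other list and signature settings, and other detection limits for single cells. Chosen after seeing the data were fits without the libraries whose expression tilted negatively with gene length, or with the tilt as a covariate, the MEF libraries split the other way, a detection limit of 1, and the single cells restricted by broadly expressed genes. The tilt is the slope of a library's log2 CPM difference from its group, or for days 5 to 9 from the reprogrammed libraries, per doubling of gene length, and 96.5% of genes had a length. Only libraries with a negative tilt past 0.1 were left out. Those with a positive tilt past 0.1 were kept, such as day 5 replicate 2 (0.15), day 9 replicate 1 (0.133) and cDC1 replicate 2 (0.165). Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.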

Results

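Bulk RNA was sequenced from 29 libraries that follow mouse embryonic fibroblasts (MEFs) made to express Pu.1 (gene Spi1), Irf8 and Batf3, transcription factors of dendritic cell development, from doxycycline-inducible lentiviruses. Doxycycline was given at 1 µg/mL from day 0. The cells carry a reporter in which Clec9a-driven Cre switches on tdTomato, a red fluorescent protein. There were 5 libraries of unsorted MEFs, and 4, 3, 3 and 3 libraries of cells sorted at days 5, 7, 8 and 9 as tdTomato+, CD45+ (gene Ptprc) and MHC-II+. Natural dendritic cells came from wildtype spleen. The 4 libraries of conventional type 1 cells (cDC1) were sorted as CD11c+ MHC-II+ CD8a+, the 4 of type 2 (cDC2) as CD11c+ MHC-II+ CD11b+, and the 3 of plasmacytoid cells (pDC) as SiglecH+ Bst2+ B220+ with intermediate MHC-II. Mean depth, in units of 1e6 counts, was 2.73 ± 1.38 for MEFs (SD, n = 5), 5.97 ± 1.14 for day 5 (n = 4), 6.97 ± 2.53 for day 7 (n = 3), 4.17 ± 1.56 for day 8 (n = 3) and 2.87 ± 0.12 for day 9 (n = 3). It was 2.72 ± 0.90 for cDC1 (n = 4), 2.62 ± 1.29 for cDC2 (n = 4) and 2.11 ± 0.59 for pDC (n = 3). These n hold for every value of a group below.

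The single-cell libraries comprise 30 wildtype MEFs, 20 tdTomato+ cells of day 3, 40 tdTomato+ cells of day 7, 36 tdTomato+ MHC-II+ cells of day 9 and 66 splenic CD11c+ MHC-II+ CD8a+ cells. The labels name no culture or animal for any library. The p-values therefore measure the spread between these libraries, which may be technical replicates. They also leave unsaid whether the MEF controls received any virus, and gene counts cannot separate transcripts of the transgenes from those of the endogenous Spi1, Irf8 and Batf3.

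The 3 transduced factors and the genes of the sort gate were abundant in reprogrammed cells and nearly absent from MEFs. At day 9 Spi1 stood at 696 ± 119 CPM against 1.85 ± 1.41 in MEFs, a log2 fold of 9.12 ± 0.30 (SE; edgeR adjusted p = 4.8e-21). Irf8 stood at 1200 ± 202 against 4.16 ± 3.24 CPM (log2 fold 8.70 ± 0.35, adjusted p = 1.9e-18) and Batf3 at 405 ± 63 against 0.967 ± 0.903 CPM (log2 fold 9.31 ± 0.28, adjusted p = 8.7e-22). Clec9a, a receptor for dead cells and the driver of the reporter, had no counts in MEFs and 62.4 ± 2.3 CPM at day 9, at least 284-fold higher. Ptprc, which encodes CD45, stood at 583 ± 41.5 CPM, with 3 counts over all MEF libraries. H2-Aa, a chain of MHC class II, had no counts in MEFs and 4250 ± 933 CPM at day 9, at least 19300-fold higher. Because these genes were delivered or used to choose the cells, their rise is not independent evidence of a change of identity.

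In the GRCm38 annotation Spi1 lies on chromosome 2 from 91082390 to 91115756, Irf8 on chromosome 8 from 120736358 to 120756694 and Batf3 on chromosome 1 from 191097847 to 191108945, all on the plus strand. Clec9a spans 129408862 to 129424763 of chromosome 6 on the plus strand. Ptprc spans 138062861 to 138175708 of chromosome 1 and H2-Aa 34282744 to 34287823 of chromosome 17, both on the minus strand. All 6 are annotated as protein-coding, and counts were summed over each gene.

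**Figure D1:**
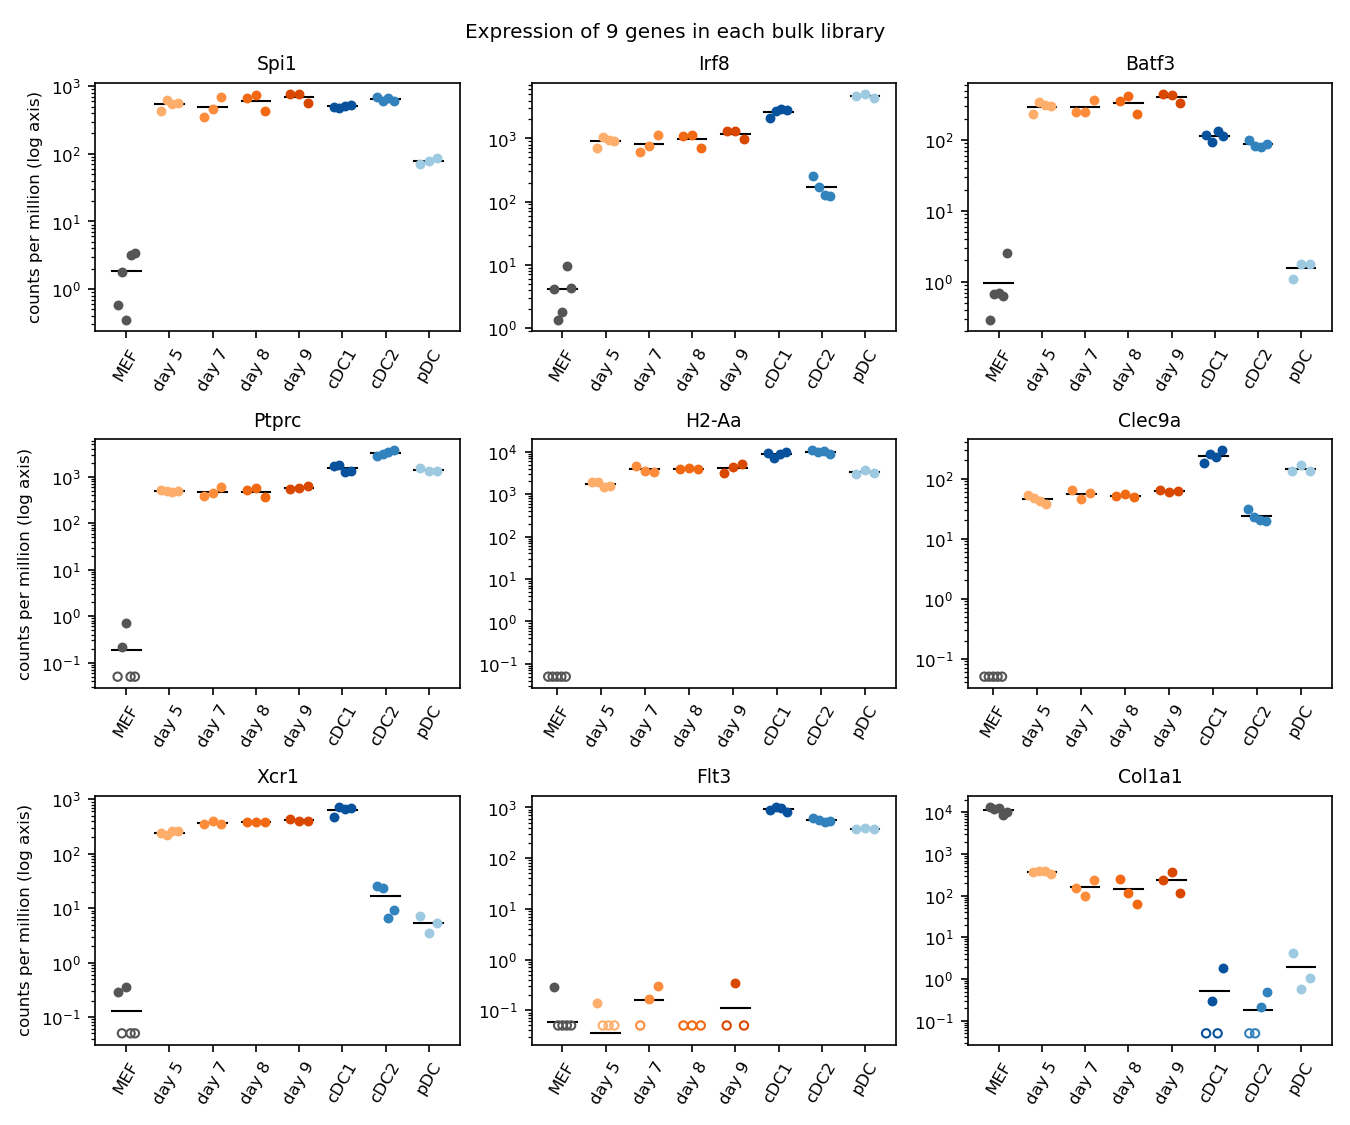
Expression of Spi1, Irf8, Batf3, Ptprc, H2-Aa, Clec9a, Xcr1, Flt3 and Col1a1 in each bulk library, in CPM on a log axis by group, with points for libraries, bars for group means and open circles for libraries with 0 counts. Spi1, Irf8 and Batf3 lie high at every reprogramming day, Flt3 is near 0 outside the splenic groups, and Col1a1 falls from 11400 CPM in MEFs to 240 CPM at day 9 and to below 1 CPM in cDC1.

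The comparison of day 9 with MEF asks how far the transcriptome of the starting fibroblasts had moved. Day 9 cells had gained antigen presentation genes, markers of cDC1 and of blood cells, and a broad set of interferon-stimulated genes, and had lost much of their matrix, contractile and cell cycle expression. Cd74, the invariant chain that escorts MHC class II, went from 0.855 ± 0.149 to 12700 ± 966 CPM (log2 fold 14.04 ± 0.19). Col1a1, the main chain of type I collagen, fell from 11400 ± 1820 to 240 ± 124 CPM (log2 fold -5.28 ± 0.45). Ccl8, a monocyte chemokine, and Mpeg1, a pore-forming protein of phagocytes, had no counts in MEFs and reached 658 ± 176 and 652 ± 31.2 CPM, at least 2990-fold and 2960-fold higher. The largest falls were Gldn, Crabp1, Actg2 and Spock3, which had no counts at day 9 and were at least 134-fold, 77.2-fold, 72.5-fold and 63.6-fold lower, and Stc1, with 1 count at day 9 against 44.3 ± 9.93 CPM in MEFs.

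Of 19 cDC1 genes tested, 16 rose, none fell and 3 did not pass, and adjusted over the list alone 17 rose (camera adjusted p = 2.6e-07). Xcr1, the chemokine receptor that marks cDC1, stood at 415 ± 19 CPM with 2 counts in MEFs, and Tlr11, a sensor of profilin, at 43 ± 8.43 CPM with none, at least 195-fold higher. Cd8a, the splenic gate gene, did not pass at 1.39 ± 0.664 against 0.540 ± 0.448 CPM (adjusted p = 0.076). Of 18 haematopoietic genes 16 rose and 16 did so adjusted over the list alone (adjusted p = 1.2e-09). Among these were Coro1a, an actin regulator of leukocytes, at 226 ± 22.7 against 0.304 ± 0.361 CPM, and Cd52 at 144 ± 55.1 CPM with no counts in MEFs, at least 653-fold higher. Of 12 genes of MHC class II presentation 9 rose (9 adjusted over the list alone, adjusted p = 4.9e-09), with Ctss, the protease that trims the invariant chain, from no counts to 142 ± 8.19 CPM, at least 646-fold higher. H2-Ab1 and H2-Eb1 stood at 4300 ± 686 and 2730 ± 452 CPM against 0.299 ± 0.325 and 0.803 ± 0.802 CPM. Clec9a, Ptprc, H2-Aa, H2-Ab1 and H2-Eb1 are members of these lists and genes of the sort gate, so the list calls depend in part on the sort.

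MHC class I and cross-presentation had 14 of 18 genes up, 1 down and 3 not past, the same counts adjusted over the list alone (camera adjusted p = 1.2e-09). H2-K1, a classical class I heavy chain, rose from 63.7 ± 11.7 to 2550 ± 20.3 CPM, and the immunoproteasome subunits Psmb8 and Psmb9 rose by 5.61 ± 0.21 and 5.72 ± 0.22 on the log2 scale. Sec22b, a vesicle fusion protein, fell by 0.36 on the log2 scale, a call lost without the low-count filter. All 20 interferon-stimulated genes rose (20 adjusted over the list alone, adjusted p = 7e-18), and their summed expression went from 223.6 ± 29.6 to 9823 ± 672 CPM. Oasl1 had no counts in MEFs and 189 ± 16.3 CPM at day 9, at least 857-fold higher, and Oas1a, an RNA-activated synthetase, stood at 148 ± 4.87 against 0.278 ± 0.478 CPM. Innate sensors had 13 of 18 up and 1 down (same adjusted over the list alone, adjusted p = 8.5e-05). They include Unc93b1, the chaperone of endosomal Toll-like receptors, at 642 ± 42.8 against 20 ± 4.09 CPM, and Ifih1, a cytosolic RNA sensor, at 91.8 ± 10.3 against 8.66 ± 1.11 CPM.

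Co-stimulation and maturation genes went both ways, with 12 of 16 up and 2 down (camera adjusted p = 0.0023, but adjusted p = 0.15 with an estimated correlation). Cd83 rose from 1.08 ± 0.748 to 97.5 ± 22.5 CPM and Cd274, the gene of the checkpoint ligand PD-L1, from 0.298 ± 0.228 to 17.6 ± 3.33 CPM, while Socs2 fell from 34.9 ± 8.67 to 3.01 ± 0.421 CPM. Cytokines and chemokines had 11 of 16 up and 4 down without a call (adjusted p = 0.056, but 0.035 with DESeq2 size factors, 0.34 with an estimated correlation and 5.8e-08 by fry, a rotation test of the list alone). Cxcl16 rose by 7.89 ± 0.19 and Cxcl5 fell by 5.15 ± 0.70 on the log2 scale. Of 14 cDC2 genes 6 rose and none fell (adjusted p = 0.0077), among them Clec12a, a C-type lectin, from no counts to 657 ± 20.6 CPM, at least 2990-fold higher, and Itgam, which encodes CD11b, with 2 counts in all MEF libraries and 1636 at day 9. Clec12a made up most of the 1164 ± 93.7 CPM of this list at day 9, and in the splenic libraries it is a gene of the pDC signature, at 536 ± 52.4 CPM in pDC against 129 ± 19.1 CPM in cDC2. Of 17 pDC genes 7 rose and 1 fell (adjusted p = 0.19). The risers include Irf7, a master regulator of interferon genes, at 1550 ± 58.8 against 5.84 ± 1.27 CPM, and Bst2, a gate gene of pDC that is also interferon-induced, at 766 ± 68.3 against 36 ± 6.8 CPM. Of 10 pan-cDC genes 5 rose and 1 fell (adjusted p = 0.061, but 0.047 with DESeq2 size factors, 0.13 with an estimated correlation and 1.9e-09 by fry). Cst3, a protease inhibitor, rose by 3.79 ± 0.25 and Zbtb46, a transcription factor of conventional dendritic cells, fell by 1.15 ± 0.27 on the log2 scale.

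Fibroblast programmes were lower at day 9. Of 20 extracellular matrix genes 16 fell and none rose (16 adjusted over the list alone, adjusted p = 2.9e-11), and their sum went from 72910 ± 10900 to 18500 ± 5930 CPM. Of 13 mesenchymal regulators and receptors 12 fell (12 adjusted over the list alone, with 1 rise there; adjusted p = 4.7e-05), such as Pdgfra, a growth factor receptor, from 138 ± 51.7 to 7.24 ± 3.98 CPM and Prrx1, a mesenchymal homeobox factor, from 245 ± 51.8 to 21.8 ± 2.38 CPM. Of 11 contractile cytoskeleton genes 10 fell (10 adjusted over the list alone, adjusted p = 1.3e-05), with Tagln from 370 ± 63.3 to 13.5 ± 7.71 CPM. All 20 cell cycle genes fell (20 adjusted over the list alone, adjusted p = 1.6e-11), among them Top2a, a topoisomerase of dividing cells, from 107 ± 25.6 to 4.42 ± 0.690 CPM and Rrm2, a subunit of the enzyme that makes deoxynucleotides, from 253 ± 27.2 to 10.7 ± 1.73 CPM. In the p53 and senescence list 8 of 13 rose and none fell (adjusted p = 0.007), with Cdkn1a, a cell cycle inhibitor, at 648 ± 146 against 238 ± 59.3 CPM and Cdkn2a at 19.3 ± 3.17 against 1.27 ± 1.45 CPM.

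Markers of other cell types were tested the same way. Of 13 macrophage genes 8 rose and none fell (10 adjusted over the list alone, adjusted p = 0.00044), with Lyz2, the macrophage lysozyme, at 334 ± 99.9 against 1.97 ± 1.31 CPM and Csf1r at 120 ± 40.7 against 2.00 ± 1.53 CPM. Of 5 endothelial genes 2 rose and 1 fell, of 4 epithelial and muscle genes 1 rose and 2 fell, and of 12 B cell genes 1 rose and 1 fell, none of these lists passing camera. No gene passed among 4 T cell, 2 NK cell, 2 neutrophil and 4 erythroid genes tested.

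In total 3746 genes rose and 3476 fell of 13434 tested at day 9 against MEF, 53.8%, and 2371 and 2356 of these by over log2 1. With library size alone in place of TMM the median gene shifted by -0.294 on the log2 scale and the split became 2766 up and 4834 down, so the balance of rises and falls rests on the scaling. With DESeq2 size factors it was 3436 up and 3838 down. The named falls and rises were far larger than that shift, except for Sec22b and some changes near log2 1.

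The earlier days were compared with MEF to ask when these changes appeared. At day 5, 3904 genes had risen and 3590 fallen. Of the 7222 genes called at day 9, 6326 were called in the same direction at day 5 (87.6%) and 4 in the opposite direction, a count made after the data were seen. If the calls were independent, 2018 and 2011 would be expected. With MEF replicates 1 and 2 used for day 5 and the other 3 for day 9 it was 5276 and 4 genes, and the other way round 5186 and 3. At day 7 the numbers were 3918 and 3757, and at day 8 they were 3917 and 3675. At day 5 Spi1 stood at 545 ± 81.9, Irf8 at 898 ± 147 and Batf3 at 296 ± 46.5 CPM, Xcr1 at 245 ± 18.7 CPM, and Col1a1 had fallen to 375 ± 30.4 CPM. By list at day 5, 13 of 19 cDC1 genes had risen (13 adjusted over the list alone, camera adjusted p = 3.7e-05), 16 of 18 haematopoietic genes (adjusted p = 2.8e-07), 9 of 12 genes of MHC class II presentation (adjusted p = 3.3e-07) and 20 of 20 interferon-stimulated genes (adjusted p = 6.5e-19). All 20 cell cycle genes had fallen (adjusted p = 4.9e-10), as had 18 of 20 extracellular matrix genes (adjusted p = 2.5e-10). These 3 splits also moved with library size alone, to 3002 up and 4597 down at day 5, 2833 and 5311 at day 7, and 2808 and 5134 at day 8, with median shifts of -0.216, -0.318 and -0.311. DESeq2 size factors shifted the median at day 5 by -0.104, with 3424 genes up and 4035 down.

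**Figure D2:**
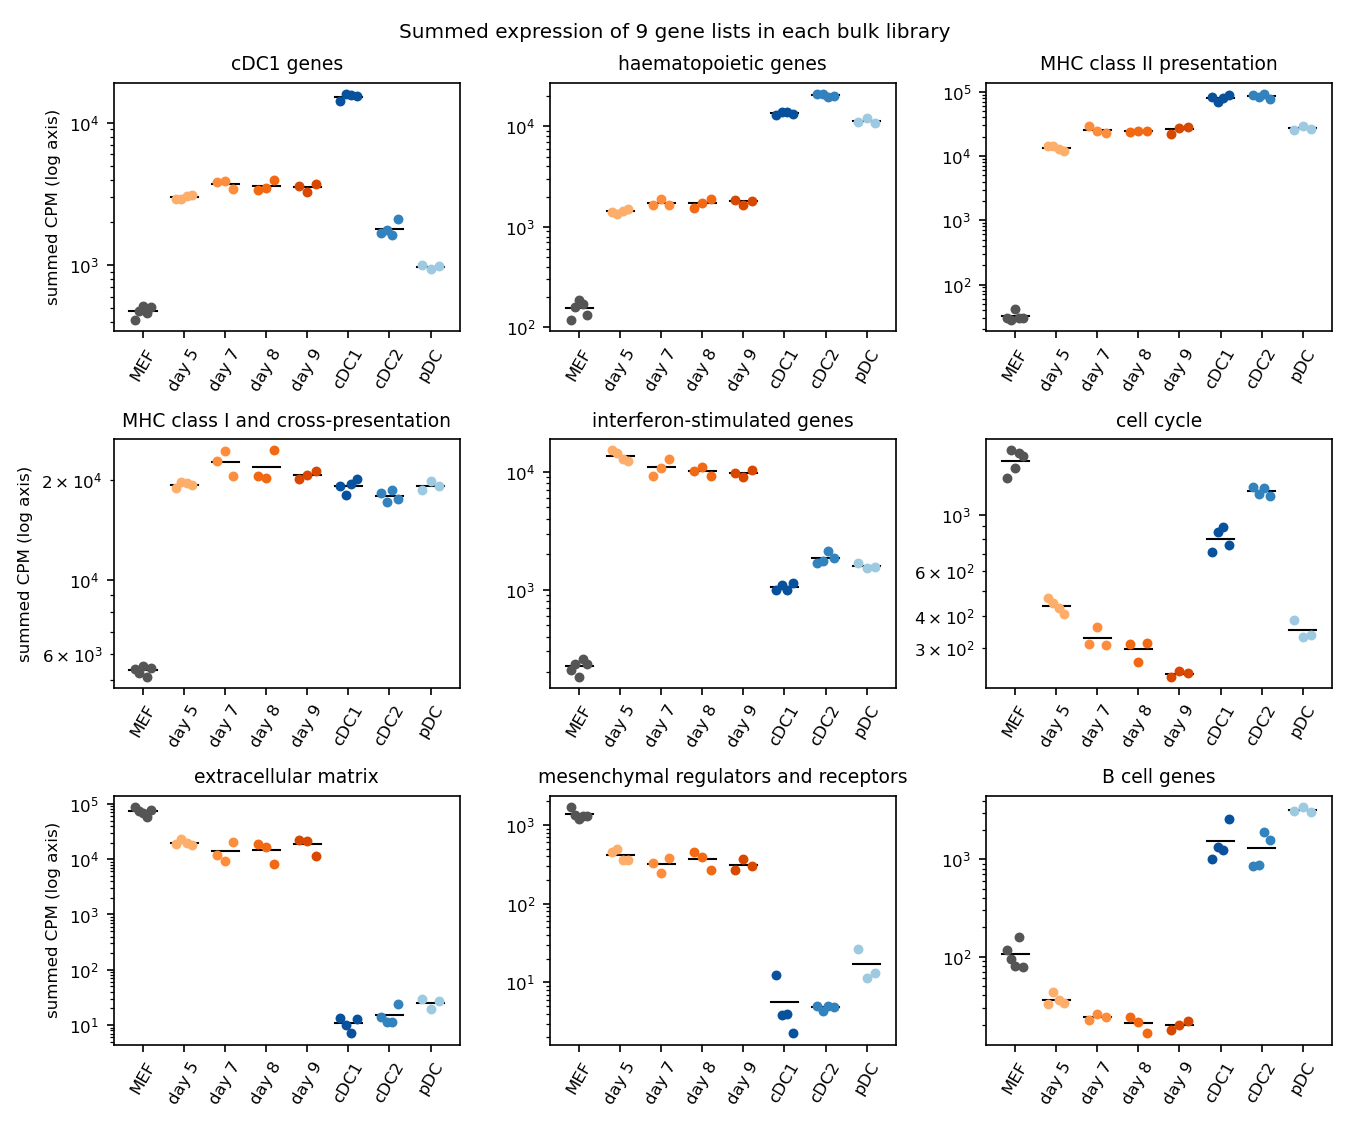
Summed expression of 9 gene lists in each bulk library, in CPM on a log axis by group, with points for libraries and bars for group means. MHC class II presentation goes from 31.84 CPM in MEFs to 13310 CPM at day 5, 25230 CPM at day 7 and 25840 CPM at day 9, against 79790 CPM in cDC1, and interferon-stimulated genes peak at day 5 at 13760 CPM.

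The comparison of day 9 with day 5, together with the trend over days 5, 7, 8 and 9, asks what went on changing among sorted cells. The lists of MHC class II presentation, cDC2 and haematopoietic genes moved up as sets, with some of their members past the threshold, and those of interferon-stimulated and cell cycle genes moved down from day 5. Clec4n, the C-type lectin Dectin-2, rose from 5.68 ± 1.13 to 219 ± 54 CPM (log2 fold 5.34 ± 0.28, edgeR adjusted p = 1.1e-13) and Cd83, a maturation marker that stabilises MHC class II, from 12.5 ± 1.39 to 97.5 ± 22.5 CPM (log2 fold 3.04 ± 0.26). Ccl5, a chemokine, fell from 87.7 ± 53.4 to 11.3 ± 3.81 CPM and C3, a complement component, from 102 ± 74.7 to 6.68 ± 3.93 CPM. Other large rises were Clec4b1, Treml4 and Cd53, and other large falls Ccnb1, Anln and Top2a. Spi1, Irf8, Batf3, Clec9a and Ptprc did not pass, with log2 folds of 0.43 ± 0.21, 0.49 ± 0.26, 0.53 ± 0.18, 0.54 ± 0.17 and 0.34 ± 0.16. With the length tilt as a covariate, in a fit of the 13 reprogrammed libraries alone, Spi1, Irf8, Batf3 and Clec9a did pass (adjusted p = 0.038, 0.016, 0.0064 and 0.019), and Clec9a also by DESeq2 (0.026) and limma-voom (0.048). The covariate fit differs from the main fit in its libraries too, so its calls cannot be credited to the covariate alone.

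Of 12 genes of MHC class II presentation 7 rose between day 5 and day 9 and 9 did so adjusted over the list alone (camera adjusted p = 3.5e-17). H2-Aa went from 1730 ± 262 to 4250 ± 933 CPM and H2-DMa, part of the peptide-loading catalyst, from 163 ± 10.1 to 376 ± 28.9 CPM. Of 19 cDC1 genes 4 rose (9 up and 1 down adjusted over the list alone, adjusted p = 1e-06), among them Tlr11 from 11.1 ± 0.891 to 43 ± 8.43 CPM and Xcr1 from 245 ± 18.7 to 415 ± 19 CPM. The call for Xcr1 (adjusted p = 0.034) was lost without any 1 of the 7 libraries (0.061 to 0.13), with library size alone (0.063) and with the replicate block (0.1). The other 2 were Cadm1 and Ppt1, and Ppt1 lost its call without day 5 replicate 2 or day 9 replicate 1 (adjusted p = 0.054 and 0.15). Of 14 cDC2 genes 5 rose (7 adjusted over the list alone, adjusted p = 1.5e-08), such as Clec4a2 by 2.56 ± 0.29 and Sirpa by 1.05 ± 0.19 on the log2 scale. Of 18 haematopoietic genes 8 rose (9 up and 1 down adjusted over the list alone, adjusted p = 6.1e-09), with Cd53 from 15.4 ± 1.76 to 87.2 ± 32.4 CPM. Of 13 macrophage genes 3 rose (3 adjusted over the list alone, adjusted p = 0.0084, but adjusted p = 0.12 with an estimated correlation), namely Lyz2, Cd68 and Csf1r, the last of these not without day 9 replicate 1 (adjusted p = 0.053).

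Of 20 interferon-stimulated genes 9 fell and none rose (13 fell adjusted over the list alone, camera adjusted p = 1.8e-15), with Gbp2 from 43.6 ± 12 to 16 ± 2.19 CPM and Cmpk2 from 84.0 ± 20.3 to 40.6 ± 4.61 CPM. Cmpk2 lost its call without day 5 replicate 1 or 2 or any 1 day 9 replicate (adjusted p = 0.05 to 0.11), and Gbp2 without day 9 replicate 2 (0.083). Of 20 cell cycle genes 12 fell (17 adjusted over the list alone, adjusted p = 3.8e-16), with Ccnb1, the mitotic cyclin B1, from 23.6 ± 4.45 to 4.18 ± 2.14 CPM. Of 16 cytokines and chemokines 6 fell (7 down and 1 up adjusted over the list alone, adjusted p = 0.0048, but adjusted p = 0.2 with an estimated correlation), with Ccl7 from 586 ± 114 to 184 ± 48.9 CPM and Csf1, the macrophage growth factor, from 327 ± 41.9 to 136 ± 21 CPM. Csf1 lost its call without day 5 replicate 2 or day 9 replicate 1 or 3 (adjusted p = 0.051 to 0.11) and with the replicate block (0.052). Innate sensors moved both ways, with Cd14 up from 33.1 ± 7.58 to 98.0 ± 19.1 CPM and 3 of 18 down, namely Nod1, Ddx58 and Ifih1. These 3 lost their call without day 9 replicate 3 (adjusted p = 0.14, 0.1 and 0.16), and Ddx58 and Ifih1 also without day 5 replicate 1 or 2 or day 9 replicate 1 or 2 (0.055 to 0.16). Ifih1 lost its call also without day 5 replicate 4 (0.052) and with the replicate block (0.067). The call for MHC class I and cross-presentation was not made, with no gene past the threshold (adjusted p = 0.93), and H2-D1 stood at 7450 ± 507 against 6500 ± 377 CPM. Further list calls that were lost are those for the transduced factors (adjusted p = 0.21 with an estimated correlation), pan-cDC genes (adjusted p = 0.074 with an estimated correlation), extracellular matrix (adjusted p = 0.53 with an estimated correlation) and contractile cytoskeleton (adjusted p = 0.34 with an estimated correlation).

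In all, 313 genes rose and 196 fell between day 5 and day 9, 3.8% of 13434. With library size alone the split was 243 up and 235 down, and without the low-count filter 358 up and 404 down. Leaving out day 9 replicate 1, 2 or 3 gave 284, 314 or 283 genes in place of 509. The trend called 315 genes up and 230 down of 12053, or 247 up and 332 down with library size alone. The total of 545 became 210 with the replicate block, 910 by DESeq2, 953 with the length tilt as a covariate and 1101 without the negatively tilted libraries, day 7 replicates 1 and 2 and day 8 replicate 3. Libraries with a positive tilt past 0.1 stayed in that fit, namely day 5 replicates 1, 2 and 3, day 7 replicate 3 and day 9 replicates 1 and 2. Clec4n had the steepest rise, at 1.38 ± 0.14 log2 per day, and C3 the steepest fall, at -1.24 ± 0.19, among the genes named. Spi1, Irf8, Batf3 and Clec9a passed in the trend with the length tilt as a covariate (adjusted p = 0.019, 0.0072, 0.0028 and 0.033) or without the negatively tilted libraries (0.05, 0.034, 0.023 and 0.02), but not in the fit of all 13. By list, 8 of 10 genes of MHC class II presentation rose over the days (9 adjusted over the list alone, adjusted p = 1.3e-10), 9 of 20 interferon-stimulated genes fell (12 adjusted over the list alone, adjusted p = 1.5e-10) and 10 of 20 cell cycle genes fell (17 adjusted over the list alone, adjusted p = 1.8e-14). The summed MHC class II list rose mainly between days 5 and 7. It stood at 13310 ± 1090, 25230 ± 3190, 24060 ± 696 and 25840 ± 3040 CPM at days 5, 7, 8 and 9. The cell cycle sum had a lower mean at each later day, at 439.3 ± 26.7, 327.2 ± 31.6, 297.3 ± 27.8 and 238 ± 5.69 CPM. For cDC1 genes 4 of 16 rose and 1 fell, namely Ifi205, an interferon-inducible gene whose call was lost with the replicate block (adjusted p = 0.06); the list gave a call (adjusted p = 2.1e-05, but adjusted p = 0.053 with an estimated correlation). The trend leans on day 5, since edgeR called no gene without the day 5 libraries, with 639 of 11332 genes at an unadjusted p under 0.05. Without day 5 replicate 1, 2, 3 or 4 it called 308, 307, 301 or 320 genes, and without day 8 or day 9 it called 353 or 1093.

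The comparison of cDC1 with MEF gives the size of the natural difference. Splenic cDC1 held more of the dendritic and haematopoietic lists, and almost no matrix expression. All 19 cDC1 genes, 18 haematopoietic genes, 10 pan-cDC genes and 12 genes of MHC class II presentation were higher in cDC1, also adjusted over the list alone (camera adjusted p = 2.7e-12, 2.5e-12, 2.8e-07 and 1.6e-10). Of 14 cDC2 genes 13 were higher (adjusted p = 8.5e-06), and of 17 pDC genes 16 were higher and 1 lower (adjusted p = 6.2e-06), with pDC genes summing to 1188 ± 157 against 556.2 ± 77.1 CPM. All 20 extracellular matrix genes and 13 mesenchymal regulators and receptors were lower (adjusted p = 4.9e-10 and 3.4e-06). In total 4864 genes were higher and 4788 lower in cDC1, 71.8% of those tested. With library size alone the median shifted by -0.145 and the split was 4303 higher and 5281 lower.

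Day 9 and cDC1 changes against MEF coincided for 4728 genes, 2283 up in both and 2445 down in both, where 1356 and 1239 would be expected if the calls were independent. Another 1008 genes changed in opposite directions. Of the genes up in cDC1, 46.9% were up at day 9, and of the genes down in cDC1, 51.1% were down. Both comparisons share the MEF libraries, which can make unrelated changes look alike. With MEF replicates 1 and 2 used for day 9 and the other 3 for cDC1, 4041 genes agreed in direction and 830 were opposed. The log2 folds of both comparisons correlated at r = 0.588, at 0.576 with this split and at 0.573 with the split reversed. Over 20 simulations of unchanged groups against the same MEFs the mean r was 0.118 and the highest 0.184. The simulated groups were drawn around the observed means of these MEFs, so the error of the shared libraries cancels. These simulations therefore cannot show how much the sharing adds to r.

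The comparison of day 9 with cDC1 asks what still separated the reprogrammed cells from the natural type. Day 9 cells kept matrix and mesenchymal expression that cDC1 lacked, had more interferon-stimulated transcripts, and had little or none of many genes of dendritic cells and other leukocytes. Flt3, the growth factor receptor of dendritic cell progenitors, stood at 923 ± 88.6 CPM in cDC1 with 1 count over the day 9 libraries. Ccr7, the receptor for migration to lymph nodes, and Btla, an inhibitory receptor, had no counts at day 9 against 662 ± 108 and 715 ± 117 CPM, at least 1900-fold and 2050-fold lower. Napsa, Asb2 and Arhgap30 also had none and were at least 1620-fold, 1370-fold and 1320-fold lower. In the other direction Postn and Col3a1, matrix proteins, Ctsk, a collagen-degrading protease, and Cav1, a membrane scaffold, had no counts in cDC1 and 636 ± 84.0, 536 ± 173, 471 ± 96.6 and 452 ± 17.1 CPM at day 9, at least 2300-fold, 1940-fold, 1700-fold and 1630-fold higher. Ccl8 was at least 2380-fold higher.

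Among the factors, Batf3 was higher at day 9 than in cDC1, at 405 ± 63 against 115 ± 17.9 CPM (log2 fold 1.95 ± 0.19, edgeR adjusted p = 2.5e-10), as was Spi1 (log2 fold 0.61 ± 0.21, adjusted p = 0.012). The call for Spi1 was lost with library size alone (0.062) and without day 9 replicate 1 (0.054) or 2 (0.056). Irf8 was lower, at 1200 ± 202 against 2650 ± 369 CPM (log2 fold -1 ± 0.27, adjusted p = 0.0021). The gate genes Clec9a, Ptprc and H2-Aa were lower, by 1.79 ± 0.17, 1.22 ± 0.17 and 0.89 ± 0.17 on the log2 scale, and Itgax, which encodes CD11c, stood at 8.73 ± 5.91 against 414 ± 47.9 CPM. Itgam was higher, by 4.24 ± 0.36 on the log2 scale.

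Of 19 cDC1 genes 16 were lower at day 9 and none higher (16 adjusted over the list alone, camera adjusted p = 5.3e-10), with Cd8a at 1.39 ± 0.664 against 891 ± 56.5 CPM and Wdfy4, needed for cross-presentation, at 3.01 ± 4.36 against 987 ± 235 CPM. Of 10 pan-cDC genes 9 were lower (adjusted p = 5.1e-07), with Zbtb46 at 4.56 ± 1.71 against 430 ± 86.0 CPM. Of 18 haematopoietic genes 17 were lower (adjusted p = 2.3e-12), with Itgb2, the shared chain of leukocyte integrins, at 3.18 ± 1.40 against 627 ± 24.9 CPM. Dock2, an activator of Rac in leukocytes, had no counts at day 9 and was at least 1200-fold lower. In MHC class II presentation 11 of 12 genes were lower and H2-DMb1 higher (adjusted p = 3.8e-07, but adjusted p = 0.065 with an estimated correlation). H2-Oa, a modulator of peptide loading, had no counts at day 9 against 281 ± 55.6 CPM. The call for H2-DMb1 was lost without day 9 replicate 2 or 3 or cDC1 replicate 2, with library size alone, with the replicate block and without the low-count filter (adjusted p = 0.059 to 0.14). In co-stimulation and maturation 13 of 16 were lower (adjusted p = 2.3e-06, but adjusted p = 0.064 with an estimated correlation), with Cd40 at 3.83 ± 1.22 against 161 ± 44.3 CPM.

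Of 20 interferon-stimulated genes 19 were higher at day 9 than in cDC1 (19 adjusted over the list alone, camera adjusted p = 1.5e-10), with Ifit2 at 4980 ± 509 against 18.8 ± 3.94 CPM and Ifi44 at 435 ± 70.4 against 4.89 ± 0.728 CPM. Their sum was 9823 ± 672 against 1058 ± 77.3 CPM. In the p53 and senescence list 12 of 13 genes were higher and Pmaip1 lower (adjusted p = 0.00013), with Phlda3 at 246 ± 8.67 against 5.11 ± 2.22 CPM. The call for Pmaip1 was lost without day 9 replicate 2 or 3 or cDC1 replicate 1 or 4 and with the replicate block (adjusted p = 0.056 to 0.17). For extracellular matrix 19 of 20 were higher (adjusted p = 5.4e-09, but adjusted p = 0.065 with an estimated correlation), for mesenchymal regulators and receptors 11 of 13 (adjusted p = 0.00063, but adjusted p = 0.069 with an estimated correlation), and for contractile cytoskeleton 8 of 11 with Cnn2 lower (adjusted p = 0.01, but adjusted p = 0.17 with an estimated correlation). Of 20 cell cycle genes 15 were lower at day 9 and 2 higher (adjusted p = 0.00013, but adjusted p = 0.081 with an estimated correlation), with Mcm5, a replication helicase subunit, at 4.62 ± 1.27 against 82.3 ± 14.4 CPM.

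The factors, MHC class I and cross-presentation, innate sensors, cytokines and chemokines, and macrophage genes gave no list call, with members both higher and lower. Class I genes were 5 higher and 7 lower of 18 (adjusted p = 0.4). Tap1, which loads peptides, stood at 255 ± 5.41 against 841 ± 151 CPM, and B2m, the light chain, at 4380 ± 533 against 2230 ± 378 CPM. Among the sensors Tlr4 was higher, at 189 ± 9.74 against 12.4 ± 2.14 CPM, and Tlr13 lower, at 0.458 ± 0.511 against 146 ± 23.3 CPM. The chemokines Ccl2 and Cxcl12 were higher at day 9, at 318 ± 76.0 and 227 ± 58.4 CPM against 1.14 ± 0.919 and 0.286 ± 0.402 CPM, and Cxcl9 was lower. Of 17 pDC genes 14 were lower (adjusted p = 0.00098, but adjusted p = 0.069 with an estimated correlation), with Siglech from 141 ± 12.2 CPM in cDC1 to no counts, at least 405-fold lower. Of 14 cDC2 genes 9 were lower and 4 higher (adjusted p = 0.046, but adjusted p = 0.081 with an estimated correlation).

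Genes listed as markers of other blood cells also differed. The CD11c+ MHC-II+ CD8a+ gate is meant to remove B and erythroid cells, and the source of these transcripts was not tested. Of 12 B cell genes 11 were lower at day 9 (adjusted p = 8.3e-05, but adjusted p = 0.23 with an estimated correlation), and their sum was 19.74 ± 2.22 against 1545 ± 697 CPM in cDC1. Ighm, the heavy chain of IgM, had 2 counts at day 9 and 959 ± 450 CPM in cDC1. It is also a gene of the pDC signature, which was made from these splenic libraries and cannot tell the source. The haemoglobin gene Hba-a2 had no counts at day 9 and 37.2 ± 52.6 CPM in cDC1, with an SD above its mean. In total 4582 genes were higher and 4103 lower at day 9 than in cDC1, 64.6% of those tested. Against cDC2 the numbers were 4869 and 4224, and against pDC 4444 and 4383. The median shifts with library size alone were -0.149, -0.174 and -0.151, and the balance then turned in all 3 comparisons, to 4139 higher and 4658 lower against cDC1, 4360 and 4807 against cDC2, and 4005 and 4874 against pDC.

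Against cDC2, day 9 cells had higher Irf8 (log2 fold 3.02 ± 0.28), Batf3 (2.39 ± 0.19) and Xcr1 (4.92 ± 0.28), while Spi1 and Itgam did not pass. Of 14 cDC2 genes 12 were lower at day 9 and 1 higher (camera adjusted p = 6.1e-06). Against pDC, Siglech had 4780 ± 493 CPM in pDC and none at day 9, 15 of 17 pDC genes were lower (adjusted p = 1.2e-08), all 20 interferon-stimulated genes were higher (adjusted p = 1.2e-08), and Bst2 did not pass at 766 ± 68.3 against 837 ± 157 CPM.

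Which natural subset day 9 cells resemble was asked with signatures made from splenic libraries alone. Of 421 cDC1 signature genes 219 rose and 59 fell at day 9 against MEF (camera adjusted p = 1.8e-07). When its genes had to differ by log2 2 it gave a call (adjusted p = 9.9e-05, but adjusted p = 0.062 with an estimated correlation). Of 495 cDC2 signature genes 150 rose and 133 fell (adjusted p = 0.46), and of 1678 pDC signature genes 331 rose and 532 fell (adjusted p = 0.052). The pDC signature fell past the threshold when its genes had to differ by log2 2 (adjusted p = 0.0052, but adjusted p = 0.13 with an estimated correlation), the range over the settings being 0.0052 to 0.36. Between day 5 and day 9, 28 cDC1 signature genes rose and 7 fell (adjusted p = 0.00086, but adjusted p = 0.099 with an estimated correlation). For the cDC2 signature 29 rose and 39 fell (adjusted p = 0.16, and 0.0024 when its genes had to differ by log2 2, but adjusted p = 0.15 there with an estimated correlation, the range over the settings being 0.0024 to 0.32), with more falls than rises although the list test points up, and for the pDC signature 44 rose and 16 fell (adjusted p = 0.16).

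Spearman similarity across genes was still highest to MEFs in the reprogrammed cells. For day 5 it was 0.814 ± 0.0092 to MEFs and 0.668 ± 0.0056 to cDC1, and for day 9 it was 0.783 ± 0.0088 and 0.673 ± 0.0054. Similarity to cDC1 was 0.665 ± 0.0065 at day 7 and 0.663 ± 0.0061 at day 8, so it hardly moved over the days. Day 9 similarity was 0.633 ± 0.0053 to cDC2 and 0.615 ± 0.0026 to pDC, and all 13 reprogrammed libraries were closer to cDC1 than to the other splenic subsets. All 5 MEF libraries were closest to cDC1 of these subsets too, so this is not specific to reprogrammed cells. With the signature genes alone it held for all 13 reprogrammed libraries and 3 of the 5 MEF libraries. Similarity to cDC1 minus similarity to MEF was 0.0357 higher at day 9 than at day 5, mostly through lower similarity to MEFs (exact permutation test, 2-sided p = 0.0286, the smallest that 35 splits allow, n = 3 and 4). With any of these libraries left out the design no longer allows a p under 0.05, and without day 9 replicate 1 or 3 the p of 0.133 was above the smallest possible, 0.067. The first principal component of the bulk libraries held 62.7% of the variance. Among the 13 reprogrammed libraries alone it held 32.9% and followed the length tilt, with day 8 replicate 3 at 62.89 (tilt -0.326), day 7 replicate 2 at 40.07 (tilt -0.26) and day 5 replicate 3 at -33.63 (tilt 0.147).

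The splenic subsets were compared with each other as a reference. Of 19 cDC1 genes 18 were higher in cDC1 than in cDC2 (19 adjusted over the list alone, camera adjusted p = 1.1e-41) and 11 of 14 cDC2 genes were lower (adjusted p = 6.8e-16). Irf8 stood at 2650 ± 369 CPM in cDC1 and 168 ± 61.7 CPM in cDC2, Cd8a at 891 ± 56.5 and 4.85 ± 2.47 CPM, and Itgam at 11.6 ± 3.27 and 223 ± 42.9 CPM. Cd8a, Itgam, Siglech and Bst2 belong to these lists and to the sort gates, so their differences follow from the sort. Against pDC, all 19 cDC1 genes were higher in cDC1 (adjusted p = 1.1e-23) and all 17 pDC genes lower (adjusted p = 2.2e-19). Clec9a was also present in pDC, at 144 ± 19.5 CPM against 239 ± 45.4 CPM in cDC1. In total 1440 genes were higher and 1514 lower in cDC1 than in cDC2, and 2480 higher and 3358 lower than in pDC. With only the libraries of cDC1 and pDC fitted, 2518 were higher and 2417 lower. The pDC libraries had more genes above 0 than others, 17962 ± 1077 against 14882 ± 260 in cDC1.

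For single cells the read depth is unknown and most values are small, with 75.5% of the values above 0 being below 1. Values above 0 therefore count a transcript assigned in part, and shares at a value of at least 1, a limit chosen after the data were seen, are given beside them. The 5 groups also differ as tables. Of 100 genes abundant in every bulk group, the median MEF cell had 98 at a value of at least 1 and the median day 3 cell 98, but the median day 7, day 9 and splenic cell had 85, 45.5 and 35.5. At least 50 of them were found in 30 of 30 MEFs, 20 of 20 day 3, 36 of 40 day 7, 10 of 36 day 9 and 16 of 66 splenic cells. A lower share at day 9 or in spleen is therefore not read as a fall, and splenic cells lacked detectable transcripts of many genes that bulk cDC1 hold.

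All 3 transduced factors were detected together in every one of the 20 day 3 cells (exact 95% interval 83.2% to 100%) and in 1 of 30 MEFs (3.3%, 0.1% to 17.2%). At day 7 they were found in 26 of 40 cells (65%, 48.3% to 79.4%), at day 9 in 32 of 36 (88.9%, 73.9% to 96.9%) and in splenic cells in 41 of 66 (62.1%, 49.3% to 73.8%). At a value of at least 1 the shares were 100%, 0%, 45%, 63.9% and 13.6% in the same order of groups. The gates differ between the days, since MHC-II was used at day 9 and not at days 3 and 7.

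**Figure D3:**
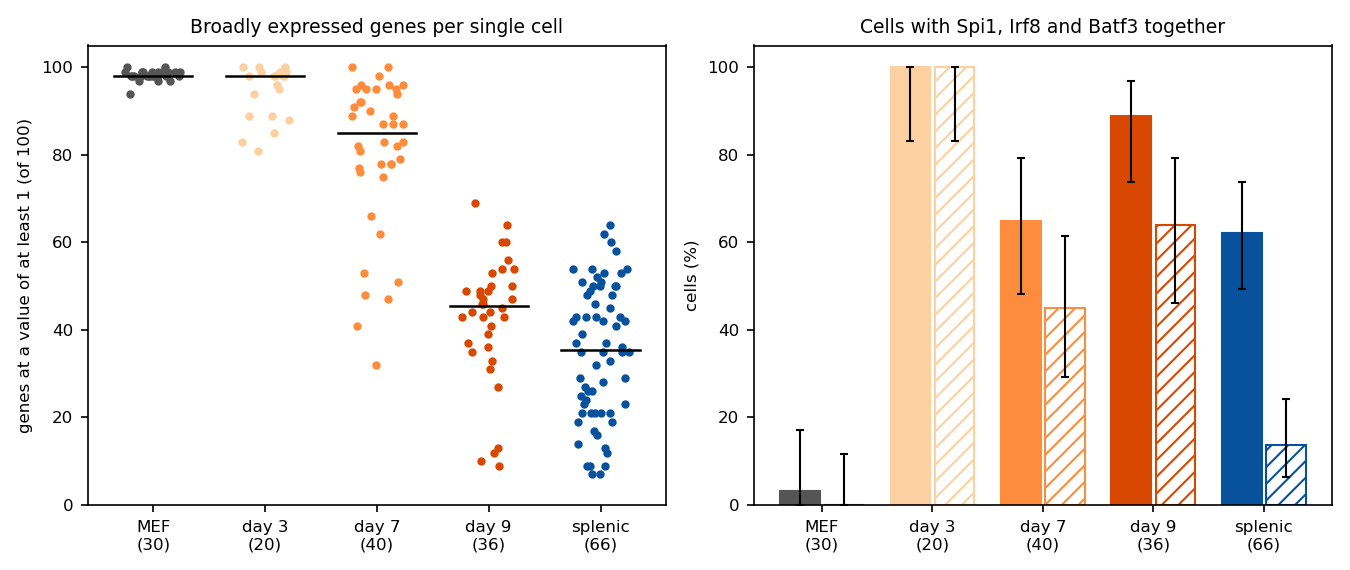
Left, number of 100 broadly expressed genes found at a value of at least 1 in each single cell, with points for cells and bars for medians. Right, percentage of cells with Spi1, Irf8 and Batf3 together, filled bars for values above 0 and hatched bars for values of at least 1, with exact 95% binomial intervals; day 3 reaches 100% by both limits and splenic cells go from 62.1% to 13.6%.

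Cd74 reached a value of at least 1 in 1 of 30 MEFs, 20 of 20 day 3 cells, 39 of 40 day 7 cells and 36 of 36 day 9 cells, with medians of 0, 73.6, 207 and 2510. In splenic cells it did so in 27 of 66. H2-Eb1 did so in 1, 11, 28, 26 and 23 cells of MEF, day 3, day 7, day 9 and spleen. Oasl1, an interferon-stimulated gene, reached it in 1 of 30 MEFs, 4 of 20, 14 of 40 and 29 of 36 reprogrammed cells of days 3, 7 and 9, and Unc93b1 in 2, 12, 19 and 29. Cdkn1a was at or above 1 in all 30 MEFs, all 20 day 3 cells, 38 day 7 cells and 32 day 9 cells. Xcr1 did so in few cells of any group, 1 of 30, 0 of 20, 6 of 40, 4 of 36 and 9 of 66. Lists summed as a median share of a cell gave 3.38% for MHC class II presentation at day 9, against 0.174% at day 3, 0.618% at day 7, 0.00588% in MEFs and 0.0255% in splenic cells, which were sorted as MHC-II+. The median number of these genes at a value of at least 1 was 5 at days 3, 7 and 9. Interferon-stimulated genes took 0.156%, 0.164% and 0.514% at days 3, 7 and 9, 0.00441% in MEFs and 0.0404% in splenic cells. The median number of them at a value of at least 1 went the other way, at 10.5, 7.5 and 7 at days 3, 7 and 9. No direction over the days is therefore read from these shares for either list.

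The genes that differed most in share of cells were mostly pseudogenes and gene models. Higher at day 9 than in MEFs were Myod1, Gm13351, Gm22771, Acsbg2 and Olfr991-ps1, and the lowest were Gm8203, Gm7536, Ube2n-ps1, Gm10108 and Gm6565, each above 0 in all 30 MEFs and in none of the 36 day 9 cells. These ranks rest on values above 0, so Myod1 is not read as switched on. The epithelial and muscle list that holds it took a median of 0.00119% of a day 9 cell against 0.00515% in MEFs. In bulk that list summed to 6.617 ± 2.72 CPM at day 9 against 27.04 ± 7.79 CPM in MEFs. Against splenic cells the highest were Gm3200, Gm11953, Gm17794, Gm10359 and Gm12671, which have identical values, and the lowest Gm10721, Gm10720, Gm47673, Gm28002 and Gm10718.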

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

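All explanations weighed in this part were tested with tests chosen after the result was seen. Single libraries far from the rest of their group were looked for in MEF, day 5, cDC1 and cDC2. Days 7, 8 and 9 and pDC, with 3 libraries each, were not searched. Over 45 measures, 180 groups of values were searched and 9 outlying values were found. Chance alone would pick about 1 in 20 such groups, which is as many.

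In MEFs, replicate 3 had 1559 CPM of pan-cDC genes where the next library had 1068, 41.2 CPM of MHC class II presentation genes where the next had 30.55, and 0.35 CPM of erythroid genes where the others had 0. MEF replicate 5 had 2.55 CPM of Batf3 where the next had 0.7. MEF replicate 4 had 6.92% of its counts in its 10 highest genes where the next had 8.57%. Among splenic cells, cDC1 replicate 3 had 255.1 CPM of erythroid genes where the next library had 40.75, cDC1 replicate 1 had 25.8 CPM of neutrophil genes where the next had 3.6, and cDC2 replicate 3 had 4.55 in units of 1e6 counts where the next had 2.1. Day 5 replicate 1 had 1.18% mitochondrial counts where the next had 0.88%.

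Symbols that had turned into dates held up to 0.415% of the counts of a bulk library. In splenic single cells the gene model Gm10800 took a median of 1.12% of a cell, against 0.0009526% in MEFs. In day 9 cells the gene model CT010467.1, annotated as ribosomal RNA, took 10.84%, against 0.1811% in MEFs.

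For 509 genes the change against MEF differed between day 9 and day 5. Day 9 and day 5 are also the ends of the trend, with Clec4n, Cd83 and H2-Aa rising and C3, Ccl5 and Ccnb1 falling. Gene length bias is excluded as the whole cause, since 509 of the 545 genes with a trend stayed past the threshold with the length tilt of each library as a covariate. A change at a single day rather than a steady course may explain the trend, since 0 genes were called by edgeR without the day 5 libraries, with 639 at an unadjusted p under 0.05, against 353 without day 8 and 1093 without day 9. A shorter span of days and fewer libraries stay open as reasons for that count, and so does a biological change between day 5 and day 7. The summed MHC class II presentation list was level from day 7 on, at 25230 ± 3190, 24060 ± 696 and 25840 ± 3040 CPM at days 7, 8 and 9. That argues against a steady course for this list. The cell cycle list was not level, at 327.2 ± 31.6, 297.3 ± 27.8 and 238 ± 5.69 CPM.

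Genes abundant in every bulk group were under a value of 1 in most day 9 and splenic single cells. Eef1a1, a translation factor, had a median of 2540 per 1e6 in MEFs and 5.286 in day 9 cells, and Rplp0, a ribosomal protein, 1625 and 0.4315. A lower total per cell in the deposited values is excluded, since the lower of the median totals of day 9 and splenic cells was 74410 against 58120 in MEFs. These totals are estimates scaled within each cell, so they cannot exclude a lower read depth or a lower yield of RNA. A few genes taking most of the counts are excluded too, since the median total outside the 10 highest genes was 0.99 times that of MEFs at day 9. What stays open is a lower read depth or yield of RNA, or a difference in how the cells were captured or their libraries made. The labels give no batch for this, and no biological explanation was tested.

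The pDC libraries had more genes above 0 than any other group. A difference in library size or depth is excluded, since thinned to 1 common total the lowest pDC library had 15663 genes and the highest other library 14337. RNA from neutrophils is excluded for pDC replicate 1, which had 16966 genes with 3.8 CPM of neutrophil genes, less than the 25.8 CPM of a cDC1 library. In pDC replicates 2 and 3 neutrophil genes stood at 90.3 and 372.9 CPM, so RNA from neutrophils may add to their counts, although the B220+ SiglecH+ gate is meant to remove such cells. After thinning these libraries had 15663 and 15939 genes, fewer than replicate 1, so more neutrophil CPM did not go with more genes than there. A true difference between pDC and conventional cells stays open and was not tested.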

How the results depend on the processing

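Chosen after seeing the data were the fits with the length tilt as a covariate or without the negatively tilted libraries, the reversed MEF split, the MEF splits of day 5 and day 9, the detection limit of 1 and the restriction to cells with broadly expressed genes. Of 4952 alternatives for 324 named-gene results, 4741 kept their direction and side of the threshold, 185 fell below it, 26 rose past it and none reversed. Cd8a at day 9 against MEF passed without MEF replicate 1 or without day 9 replicate 3, with log2 folds of 2.01 and 1.8. Leaving out 1 library moved the counts against MEF to 6944 to 7280 at day 5, 6982 to 7704 at day 7, 6799 to 7606 at day 8, 6633 to 7102 at day 9 and 9266 to 9485 for cDC1. Day 9 went to 8170 to 8515 against cDC1, 8645 to 8920 against cDC2 and 8336 to 8576 against pDC, and cDC1 to 2514 to 2816 against cDC2 and 5030 to 5691 against pDC. Day 9 against day 5 gave 283 to 402 genes, with 284, 314 and 283 without day 9 replicate 1, 2 and 3, and 910 with the tilt as a covariate, 463 of the 509 among them. The trend gave 301 to 614 genes, with 308, 307, 301 and 320 without day 5 replicate 1, 2, 3 and 4. It gave 910 by DESeq2, 210 with the replicate number as a block, 1101 without the negatively tilted libraries and 953 with the tilt as a covariate, which kept 543, 206, 532 and 509 of the 545. Without day 5, 8 or 9 it gave 0, 353 or 1093 genes, and edgeR had 639 at an unadjusted p under 0.05 without day 5. With an estimated correlation 6 in place of 12 lists passed for day 9 against day 5, 5 in place of 10 for the trend, and 5 in place of 15 for day 9 against cDC1, where fry called 23. The pDC signature at day 9 against MEF and the cDC2 signature at day 9 against day 5 passed at log2 2 (adjusted p = 0.0052 and 0.0024), though not with an estimated correlation there (0.13 and 0.15), and with it the cDC1 signature failed at day 9 against day 5 (0.099) and, at log2 2, against MEF (0.062). The similarity difference of day 9 and day 5 ranged from 0.0302 to 0.0439 with 1 library left out, where too few splits remain for a p under 0.05, and without day 9 replicate 1 or 3 p was 0.133 where 0.067 was possible. Beyond log2 1, 3031 genes changed the same way at day 9 and in cDC1 and 387 opposite ways, a stricter limit. All 3 factors were found in 63.9% of day 9 cells at a value of at least 1, 63.9% at 2, 67.7% after thinning and 100% of the 10 cells with broadly expressed genes, against 88.9%. Apart from the stricter limits named, the cause was not tested. Depth limits genes under a floor of 0.48 CPM in pDC and 0.13 CPM at day 5.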

Other observations

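The tests of other splits were chosen after the result was seen for the comparisons of day 5, 7, 8 and 9 with MEF and of day 9 with day 5, cDC1, cDC2 and pDC. Splenic cDC1 and cDC2 differed beyond their own marker lists. Of 20 interferon-stimulated genes 16 were lower and 2 higher in cDC1 than in cDC2 (16 and 2 adjusted over the list alone, camera adjusted p = 2.1e-12), of 18 innate sensors 10 were lower (12 adjusted over the list alone, adjusted p = 1.1e-08), and of 13 macrophage genes 12 were lower (13 adjusted over the list alone, adjusted p = 1.8e-14). The macrophage list summed to 694.7 ± 74.4 CPM in cDC1, 4737 ± 299 CPM in cDC2 and 1553 ± 86 CPM in pDC. Of 18 genes of MHC class I and cross-presentation 10 were higher in cDC1 and 2 lower (adjusted p = 0.012, but adjusted p = 0.18 with an estimated correlation). Against pDC, cDC1 had 11 of 12 genes of MHC class II presentation higher (adjusted p = 1.9e-10), 14 of 16 co-stimulation and maturation genes higher (adjusted p = 1.7e-11) and 18 of 20 cell cycle genes higher (adjusted p = 2e-09).

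Genes listed as markers of other cell types had counts in the splenic libraries. The sort gates are meant to remove such cells, but their purity was not tested. Ighm, Kdr and Acta1 of these lists are also genes of the pDC signature. That signature was made from these same libraries, so membership cannot tell the source. The source of the transcripts is open and was not tested. B cell genes summed to 1545 ± 697 CPM in cDC1, 1301 ± 531 CPM in cDC2 and 3213 ± 197 CPM in pDC, with Ighm at 959 ± 450, 739 ± 199 and 2890 ± 158 CPM. Erythroid genes summed to 82.25 ± 116 CPM in cDC1, 87.9 ± 33.4 CPM in cDC2 and 16.18 ± 3.49 CPM in pDC. T cell genes stood at 31.46 ± 7.51, 23.51 ± 3.19 and 30.99 ± 5.78 CPM in the same order, and NK cell genes at 7.256 ± 2.74 CPM in cDC1 and 16.7 ± 6.83 CPM in pDC. Endothelial genes summed to 183.8 ± 41.6 CPM in cDC1 and 430.9 ± 28.7 CPM in pDC, and epithelial and muscle genes to 18.41 ± 4.89 and 419.5 ± 50.8 CPM.

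Other splits of the same libraries into groups of the same sizes were counted with 2-group fits. The other splits mix libraries of both groups, which widens the spread within groups and lowers the calls. For groups far apart a first rank of the real split was therefore nearly fixed in advance. The labels name no culture or animal, so chance between cultures or animals was not tested. Only 1 split, the real one, gave as many genes in each comparison below. That was 1 of 100 splits for day 5 against MEF, with 7462 genes and 4117 in the highest other split, and 1 of 100 for cDC1 against MEF, with 8565 and 3332. It was 1 of 56 for day 7, day 8 and day 9 against MEF, with 6940, 6845 and 6731 genes and 0 in every other split. It was 1 of 35 for day 9 against day 5, with 610 genes and 35, for day 9 against cDC1 and cDC2, with 7447 and 8250 genes and 0, and for cDC1 against cDC2 and pDC, with 2491 and 4935 genes and 0 and 2. For the trend it was 1 of 100 orders of the days, with 545 genes and 1 in the highest other. For day 9 against pDC the 10 splits are too few for a share under 0.05, with 8199 genes in the real split and 0 in the highest other.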
